A study of Mus musculus with 6 samples.

How the data were processed

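Total RNA of mouse (C57BL/6) mesoderm progenitor cells was sequenced in 6 libraries, 1 per condition. The conditions were 0 h and 96 h in culture with no growth factor, BMP4 for 5 h, BMP4 for 11 h, BMP4 with FGF8 for 5 h, and BMP4 with FGF4 for 11 h. Per the labels, growth factors were added after 96 h, so that the 5 h and 11 h libraries are labelled 101 h and 107 h in culture. Cells grew in serum-containing medium on a layer of mouse embryonic fibroblasts whose division had been blocked with mitomycin C, per the labels' protocols. Libraries were made with a stranded total RNA kit, per the labels' protocols.

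The deposited table holds raw counts of reads per gene, made by the authors and not normalized. The submitters' processing notes name cutadapt, STAR 2.4.0e, HTSeq, DESeq and the genome build mm10, without giving the role of each. Counting settings are not given in the sources used here. Near-identical gene copies, such as Hba-a1 and Hba-a2, carry almost the same counts in each library, so copies of such families cannot be told apart. Between 65.4% and 70.9% of the values from 1 to 20 are even numbers, and whether both reads of a pair were counted is not stated.

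The table lists 19342 gene names beside 6 columns of counts, and the 4 growth factor columns are out of register with the names. The 2 untreated columns have as many values as there are names, while the others hold 19415 (BMP4 5 h), 19686 (BMP4 11 h), 19437 (BMP4 with FGF8) and 19826 (BMP4 with FGF4) values. Read row by row, log2 counts of the growth factor columns correlated with the untreated columns across genes at r between 0.046 and 0.136. Each column was therefore matched to the names by an order-preserving alignment, which lets a column skip or add rows and charges a matched row only for lying outside the range of the 2 untreated libraries. The names were sorted without regard to letter case before the alignment. After placement, r across genes was between 0.963 and 0.992. The alignment seeks rows of like level, so this r does not check the names independently. A gene was kept where, in all 4 columns, any other row cost at least 5 units more and, for genes far from both untreated libraries, no row within 3 positions pointed to an exchange. The 2 columns of 5 h, and those of 11 h, also had to pair the same rows when aligned directly with each other. This left 17059 genes, which hold 99.1% to 99.2% of the counts of each library.

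The placement was tested on simulated columns with 200 changed genes each. There, 96.9% of 13827 expressed genes were kept in all 4 columns, and 99.8% of those kept were right. Of genes changed 4-fold or 8-fold, between 90.1% and 98.5% were kept per column. Aligning the 2 columns of 5 h directly with each other gave the same row pair for 99.9% of 13708 genes. Genes far outside the range of both untreated libraries are placed less often, so strong changes beyond that range are the least complete part of the results, and values between both untreated libraries are favoured. Genes of the fixed lists that were not securely placed, for reasons not tested per gene, include Fgf8, Fos, Egr1, Jun, Smad6, Smad7, Sox9 and Hspa1a.

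Counts of the kept genes were scaled by TMM effective library sizes (edgeR 4.0.16 in R 4.3.3) and are given as CPM, the library-scaled counts of edgeR. Genes with at least 1 CPM in at least 1 library were analysed, which left 13917. The log2 ratio between 2 libraries was taken after adding 0.5 CPM to both, which understates the change of weakly expressed genes. A gene was counted as different where this ratio was at least 2-fold and the exact (Clopper-Pearson) 95% counting interval of the plain ratio excluded 1. At these depths the interval removed no gene from any count, so the fold alone set the calls. On 2 simulated libraries for 13917 genes, 98% of genes raised 4-fold and 88% of genes lowered 4-fold were called, and 94.9% of the intervals held the true ratio. With 1 library per condition there is no replicate, the ratios between 2 libraries carry no p-value, and all intervals cover counting error only. The intervals would be too narrow if both reads of a pair were counted.

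Before the data were examined, 31 gene lists, the comparisons and the rule for named genes were fixed. A list's median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 40 bins, and the list is said to stand apart outside the central 95% of these. This describes the 2 libraries and does not test the conditions. Some lists share members, such as Nrarp (Notch and presomitic), Cyp26a1 (retinoic acid and tailbud) and Hoxd11 (posterior Hox and intermediate mesoderm). Their medians are therefore not independent. The genes named per comparison are up to 8 in each direction with the counting interval farthest from 1 and a mean of at least 5 CPM, without predicted, RIKEN, small RNA, pseudogene and ribosomal RNA symbols. Up to 4 members are named from each list that stands apart or that the comparison is about, and 11 fixed genes are followed in all libraries.

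The 4 BMP4 libraries were also fitted together with edgeR's quasi-likelihood test, with time and FGF addition as additive terms and Benjamini-Hochberg adjustment. This fit did not use the 1 CPM filter but edgeR's filterByExpr on the 17059 kept genes, which left 16936. This leaves 1 residual degree of freedom, treats FGF8 at 5 h and FGF4 at 11 h as 1 condition, and is not a replicate test of either. On simulated counts of 16927 genes with 200 changed and a coefficient of variation of 0.1, the fit recovered 100% of 2-fold and 100% of 4-fold changes, with 4 unchanged genes called. The common coefficient of variation of the real fit was larger, at 0.144, and was not simulated. Alternatives were DESeq2 1.42.0 and its size factors, total counts, no filter, at least 5 CPM, 2 CPM added and the fold alone. After the data had been seen, a placement margin of 10, placement on the 96 h column alone, halved counts and all named rows of the untreated columns were added, as were comparisons with 0 h. The alignment and ratios ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0. Gene positions are from GENCODE vM21 on GRCm38, the assembly also called mm10.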

Results

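RNA of mouse tailbud mesoderm progenitors was compared across 6 libraries to see how culture and added growth factors alter their state. Total counts were 219269083 (0 h untreated), 272743104 (96 h untreated), 218825816 (BMP4 5 h), 179196459 (BMP4 11 h), 222676298 (BMP4 with FGF8 5 h) and 206470866 (BMP4 with FGF4 11 h). At these depths 3 counts correspond to between 0.0111 and 0.0181 CPM. Each condition had 1 library, so no difference below has a replicate check, and the libraries labelled 5 h and 11 h have no untreated control of the same culture time. The growth factor columns of the deposited table had to be matched to gene names, and genes that could not be placed securely are not analysed here.

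After 96 h of culture without growth factors, genes of the tailbud and presomitic mesoderm were far lower than at 0 h, while red blood cell, endothelial, lateral plate and fibroblast genes were higher. T (Brachyury), a T-box factor of the primitive streak and tailbud (chromosome 17, 8434423 to 8442496), fell from 83.3 to 7.66 CPM, or 10.4 to 11.4-fold by the counting interval. Tbx6, which directs presomitic mesoderm fate (chromosome 7, 126781483 to 126785560), fell from 40.7 to 0.586 CPM, and Msgn1 (chromosome 12, 11208360 to 11208972) from 23.2 to 0.151 CPM. Hand1, a lateral plate and heart factor (chromosome 11, 57828705 to 57832818), rose from 1.56 to 31.6 CPM, 18.2 to 22.6-fold by the counting interval. In all, 537 of 13917 genes were at least 2-fold higher and 328 at least 2-fold lower. These counts were 295 and 185 with 2 CPM added and 349 and 211 with a filter of at least 5 CPM, and 188 were lower with placement on the 96 h column alone.

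Of 16 tailbud and primitive streak genes, 11 fell and none rose, with a median log2 ratio of -2.43, below all 10000 random lists. Fgf17 fell from 38.2 to 0.479 CPM, Cdx4 from 60.6 to 2.61, the retinoic acid-degrading enzyme Cyp26a1 from 35.6 to 1.71, and Cdx2 from 58.4 to 4.17 CPM. Of 19 presomitic genes 14 fell (median -2.42), among them the segmentation clock gene Hes7, from 13.96 to 0.299 CPM, and the Notch ligand gene Dll3, from 49.0 to 3.36 CPM. Posterior Hox genes (groups 10 to 13) fell in 9 of 10 cases (median -2.43), with Hoxd11 at 63.0 and then 3.81 CPM and Hoxc10 at 103 and then 10.9 CPM. Trunk Hox genes (groups 6 to 9) had a smaller median of -0.94 with 6 of 12 lower, and anterior Hox genes (groups 1 to 5) a median of -0.65 with 5 of 15 lower. Of 16 intermediate mesoderm and nephric genes 8 fell (median -1.02). Pax2, a kidney and intermediate mesoderm factor (chromosome 19, 44756045 to 44837871), fell from 52.7 to 0.778 CPM, Pax8 from 6.94 to 0.332 CPM and Sall1 from 189 to 54.1 CPM. Osr1, a factor of intermediate and lateral mesoderm, and Foxf1, a lateral plate factor, had log2 ratios of -1.15 and 1.68 after culture, 1.04 and -1.63 with BMP4 at 5 h and 0.27 and -0.40 with BMP4 at 11 h over 96 h. With FGF8 added they were at -0.06 and 0.03, and with FGF4 added at -0.64 and 0.32, over BMP4 alone. Gad1 and Kcnab3 were also among the strongest falls, at log2 ratios of -4.21 and -3.59.

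Of 17 FGF/ERK feedback and target genes 7 fell (median -0.79), including Spry4, an inhibitor of receptor tyrosine kinase signalling (27.8 to 4.70 CPM), Etv4 (37.2 to 8.32 CPM) and Il17rd (99.4 to 27.3 CPM). WNT target genes fell in 5 of 13 cases (median -0.34), with Dkk1 at 16.5 and then 2.20 CPM and Sp5 at 12.8 and then 2.93 CPM. The Notch target list had a median of -0.59, with 2 of 10 lower, led by Nrarp (59.4 to 16.9 CPM). The glucose transporter gene Slc2a3 fell from 281 to 93.0 CPM in a glycolysis and hypoxia list with a median of -0.23 and 1 of 17 lower. The BMP/SMAD list did not stand apart, with a median of 0.11 at the 94.2th percentile and 1 of 14 lower (Dlx5, 2.77 to 0.804 CPM, named after its values were seen), and Id1, Msx1 and Msx2 had log2 ratios of -0.22, 0.34 and 0.17. Among p53 targets (median -0.13, 1 of 15 lower) Pmaip1 fell from 29.1 to 1.70 CPM.

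All 13 red blood cell genes analysed rose (median 3.88). The embryonic globin gene Hba-x rose from 1.80 to 309 CPM, Hbb-bh1 from 1.72 to 241 CPM, Hbb-y from 2.38 to 296 CPM and the anion exchanger gene Slc4a1 from 0.0457 to 74.0 CPM. Adult-type Hba-a1 and Hba-a2, which share reads, both went from 6.90 to 2109 CPM, and Hbq1b and Hemgn, outside the list, rose to 153 and 12.9 CPM. Of 17 endothelial genes 13 rose and Lmo2 fell, from 34.2 to 6.89 CPM (median 2.21), led by Tal1 (0.485 to 14.2 CPM), the vascular cadherin gene Cdh5 (1.25 to 21.1 CPM), Tie1 and Tek. Lateral plate genes rose in 11 of 17 cases (median 1.69), with Wnt2 at 0.750 and then 15.7 CPM and Gata4 at 0.475 and then 10.9 CPM. Of 15 fibroblast genes, chosen as markers of the feeder layer, 10 rose (median 1.90), including Lum (0.247 to 30.2 CPM), Postn (2.60 to 102 CPM) and Col3a1 (25.4 to 251 CPM). TGF-beta and serum response genes rose in 6 of 11 cases (median 1.10), led by Acta2 (12.3 to 62.6 CPM) and Tagln (7.51 to 26.0 CPM).

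The somite and dermomyotome list had a median of 0.12 with 4 of 16 higher, among them Meox2 (4.26 to 15.4 CPM) and Ebf3 (5.77 to 19.2 CPM). Sclerotome and cartilage genes were higher in 4 of 13 cases (median 0.61), with Pax1 going from 5.06 to 26.2 CPM, and skeletal muscle genes in 4 of 9 cases (median 0.93), with Actc1 going from 6.88 to 46.1 CPM. Neural crest genes were higher in 3 of 9 cases (median 0.28), Sox10 going from 3.28 to 8.99 CPM. Neural genes went both ways, with 3 higher and 2 lower of 16 (median 0.14), and Olig2 rose from 3.11 to 12.9 CPM. In the endoderm, notochord and epithelial list 4 of 17 genes rose and 5 fell (median -0.25), Epcam falling from 9.58 to 4.33 CPM. Cell cycle genes did not stand apart (median 0.01 over 26 genes).

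**Figure D1:**
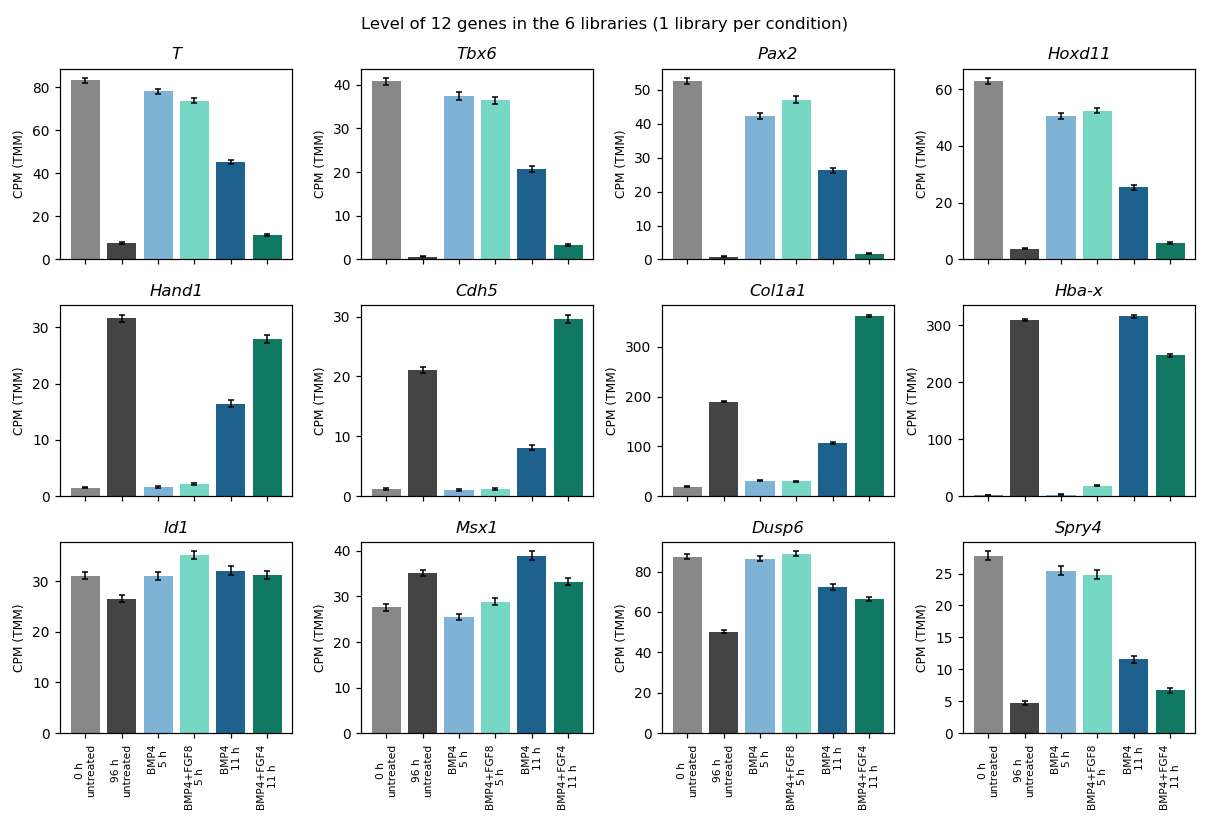
Level of 12 genes in each library, in CPM after TMM scaling, with bars starting at 0 and error lines giving the exact 95% counting interval of the single library. T, Tbx6, Pax2 and Hoxd11 are high at 0 h and at 5 h and low at 96 h, while Hand1, Cdh5, Col1a1 and Hba-x show the opposite, and Id1 lies between 26.6 and 35.1 CPM throughout.

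The library labelled BMP4 5 h had higher levels of most tailbud and presomitic genes, and lower levels of red blood cell genes and most endothelial genes, than 96 h untreated. Tbx6 was at 37.4 CPM against 0.586, T at 78.2 against 7.66, Msgn1 at 18.3 against 0.151, and Pax2 at 42.4 against 0.778 CPM. Hba-x was at 3.08 against 309 CPM, Hand1 at 1.70 against 31.6, and Cdh5 at 1.02 against 21.1 CPM. There were 314 genes at least 2-fold higher and 454 at least 2-fold lower. With 2 CPM added these counts were 187 and 258, with at least 5 CPM 286 were lower, and with placement on the 96 h column alone 189 were higher. Of the 328 genes that had fallen by 96 h, 269 were among those higher with BMP4 at 5 h, and of the 537 that had risen, 411 were among those lower. Independent lists would share 7.40 and 17.5 genes, and unchanged libraries simulated with a coefficient of variation of 0.2 shared 11.4 and 6.05. Each overlap uses the same 96 h library in both of its comparisons. The same library differed at least 2-fold from 0 h untreated in 47 genes upward and 12 downward, a comparison chosen after seeing the data.

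By group, 11 of 16 tailbud genes (median 2.34) and 15 of 19 presomitic genes (median 2.405) were higher with BMP4 at 5 h than at 96 h untreated. Fgf17 was at 33.4 CPM, Cdx4 at 51.1, Cyp26a1 at 30.3, Cdx2 at 51.7, Hes7 at 12.7 and Dll3 at 44.3 CPM. Posterior, trunk and anterior Hox lists had medians of 2.21, 0.86 and 0.59, with 9 of 10, 5 of 12 and 3 of 15 members higher. Intermediate mesoderm genes had a median of 0.66 with 6 of 16 higher, Hoxd11 at 50.5 and Sall1 at 178 CPM. FGF/ERK genes were higher in 7 of 17 cases (median 0.78), with Spry4 at 25.4 against 4.70 CPM and Etv4 at 35.1 against 8.32 CPM. WNT, Notch and retinoic acid lists stood above random lists with medians of 0.40, 0.53 and 0.22 and 5 of 13, 3 of 10 and 3 of 12 higher, including Dkk1 (10.3 against 2.20 CPM), Nrarp (57.1 against 16.9 CPM) and Cyp26a1 (30.3 against 1.71 CPM). Nrarp is also in the presomitic list and Cyp26a1 in the tailbud list. With placement on the 96 h column alone the retinoic acid median reversed to -0.15.

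The BMP/SMAD list stood slightly below random lists, with a median of -0.15 at the 1.06th percentile and 1 of 14 genes higher, Dlx5 at 3.33 against 0.804 CPM. Id1, a direct target of BMP signalling (chromosome 2, 152736251 to 152737410), had a log2 ratio of 0.22, Msx1 of -0.45 and Msx2 of -0.28. Smad9, at 1.90 against 3.78 CPM, had the lowest ratio of the list. All 13 red blood cell genes were lower (median -4.99), and Hemgn had 0 counts with BMP4 at 5 h, which makes it at least 946-fold lower against a floor of 3 counts. Endothelial genes were lower in 14 of 17 cases, with Lmo2 higher (median -2.39), with Tal1 at 0.309 against 14.2 CPM, lateral plate genes in 12 of 17 (median -1.65), with Gata4 at 0.427 against 10.9 CPM, and fibroblast genes in 7 of 15, with Thy1 and Fbln2 higher (median -0.89), with Lum at 1.17 against 30.2 CPM. Skeletal muscle genes were lower in 5 of 9 cases (median -1.20), sclerotome genes in 4 of 13 (median -0.56) and somite genes in 4 of 16 (median -0.17), with Ttn, Pax1 and Meox2 at log2 ratios of -2.50, -2.35 and -1.85. The TGF-beta and serum response list did not stand apart (median 0.03, 1 of 11 higher and 3 lower), and p53 targets did, with a median of 0.22 and 2 of 15 higher, Pmaip1 at 26.8 and Cdkn1a at 11.1 CPM. The sex-linked list stood below random lists (median -0.50), with Ddx3y at 14.3 against 23.5 CPM, while Xist, its 1 called member, was higher at 212 against 79.8 CPM.

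The BMP4 11 h library held tailbud and presomitic genes at intermediate levels, together with globin levels close to those of 96 h untreated. Tbx6 was at 20.7 CPM against 0.586 at 96 h, T at 45.2 against 7.66 (5.62 to 6.20-fold by the counting interval), Pax2 at 26.3 against 0.778, and Fgf17 at 14.01 against 0.479 CPM. A total of 298 genes were at least 2-fold higher and 35 at least 2-fold lower than at 96 h. With 2 CPM added these counts were 140 and 12, with at least 5 CPM 178 were higher, and with placement on the 96 h column alone 20 were lower. Myh6, the atrial myosin heavy chain gene, was at 6.33 against 25.9 CPM, Myh7 at 2.16 against 8.04, Myl7 at 5.12 against 13.9, Tnnt2 at 3.88 against 10.1, and Afp, an embryonic liver and yolk sac gene, at 2.87 against 8.79 CPM.

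Tailbud genes were higher than at 96 h in 10 of 16 cases (median 1.43) and presomitic genes in 10 of 19 (median 1.41), with Msgn1 at 6.56, Hes7 at 7.08, Dll3 at 22.4, Cdx4 at 23.1 and Cyp26a1 at 13.3 CPM. Posterior Hox genes were higher in 8 of 10 cases (median 1.47), with Hoxd11 at 25.3 and Hoxc10 at 49.5 CPM, trunk Hox genes in 4 of 12 (median 0.65) and anterior Hox genes in 1 of 15 (median 0.52). Of 16 intermediate mesoderm genes 6 were higher (median 0.28). FGF/ERK genes were higher in 5 of 17 cases (median 0.78), led by Ier3, Etv4, Dusp4 and Spry4 at log2 ratios of 1.43, 1.28, 1.27 and 1.21. The BMP/SMAD list stood above random lists, with a median of 0.21 at the 99.5th percentile and 1 of 14 higher. That gene was Id4, at 5.21 against 1.32 CPM, while Id3, Id1, Msx1 and Msx2 had log2 ratios of 0.39, 0.27, 0.15 and -0.05.

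Of 15 p53 targets 5 were higher (median 0.26), with the cell cycle inhibitor gene Cdkn1a at 25.1 against 4.74 CPM, Sesn2 at 27.4 against 7.05, Bbc3 at 8.75 against 3.08 and Pmaip1 at 15.1 against 1.70 CPM. Pmaip1 was higher still at 0 h and with BMP4 at 5 h (29.1 and 26.8 CPM), and the p53 list did not stand apart for 11 h over 5 h (median 0.09). The p53-induced noncoding RNA gene Trp53cor1 was at 11.9 against 0.453 CPM. Immediate early and dissociation genes had a median of 0.46 with 2 of 8 higher, Atf3 at 17.1 against 5.02 and Btg2 at 26.8 against 11.4 CPM, Btg2 being at 36.5 CPM at 0 h and 40.1 CPM with BMP4 at 5 h. Only these 8 of the list's 18 genes were analysed. Fos, Fosb, Jun, Junb, Egr1, Egr2, Egr3, Nr4a1, Hspa1a and Hspa1b were not securely placed, so the median leaves them out. TGF-beta and serum response genes were higher in 4 of 11 cases (median 0.21), led by Ctgf (33.7 against 8.09 CPM) and Cyr61 (96.4 against 37.2 CPM). Lateral plate, endothelial and fibroblast lists stood below random lists with medians of -0.46, -0.65 and -0.44 and 2 of 17, 4 of 17 and 2 of 15 lower, while Lmo2, Runx1 and Thy1 were higher, with Gata4 at 3.81 against 10.9 CPM, Cdh5 at 8.10 against 21.1 and Lum at 13.6 against 30.2 CPM. Red blood cell genes had a median of -0.34 with none called, and the cell cycle list a median of -0.09, led by Top2a (244 against 307 CPM).

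Both BMP4 libraries were higher than 96 h untreated in 154 of the same genes and lower in 34, against 6.72 and 1.14 for independent lists. Simulated unchanged libraries with a coefficient of variation of 0.2 shared 11.9 and 5.15, and both comparisons use the same 96 h library. The shared counts were 78 and 12 with 2 CPM added and 77 and 19 with placement on the 96 h column alone. Of the 328 genes lower at 96 h than at 0 h, 133 were higher with BMP4 at 11 h, and 33 of the 35 genes lower with BMP4 at 11 h had been higher at 96 h. Independent lists would share 7.02 and 1.35, and unchanged libraries simulated at 0.2 shared 10.8 and 5.10, with the 96 h library again in both comparisons.

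Set directly against BMP4 5 h, the BMP4 11 h library had far more red blood cell, endothelial and lateral plate transcripts and fewer tailbud transcripts. Hba-x was at 316 against 3.08 CPM, Hba-a1 and Hba-a2 at 1993 against 8.28, Hbq1b at 205 against 0.273 and Slc4a1 at 51.6 against 0.264 CPM. Hand1 was at 16.4 against 1.70 CPM (8.64 to 10.8-fold by the counting interval) and Wnt2 at 8.84 against 0.809 CPM. Nkx1-2, a marker of axial progenitors, was at 5.59 against 18.7 CPM, Cdx2 at 18.4 against 51.7, Msgn1 at 6.56 against 18.3, Hes3 at 5.17 against 14.5 and Cyp26b1 at 4.98 against 15.8 CPM. In all, 345 genes were at least 2-fold higher and 41 lower, which became 143 and 18 with 2 CPM added and 203 and 26 with at least 5 CPM, and 16 were lower with placement on the 96 h column alone. Higher at 11 h were 13 of 13 red blood cell genes (median 4.66), 14 of 17 endothelial genes (median 1.59), 10 of 17 lateral plate genes (median 1.20), 6 of 15 fibroblast genes (median 0.30) and 4 of 9 skeletal muscle genes (median 0.99). Lower were 6 of 16 tailbud genes (median -0.79), 4 of 19 presomitic genes (median -0.81) and 1 of 10 posterior Hox genes (median -0.70).

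The BMP/SMAD list had a median of 0.28, with Id4 higher and Dlx5 lower, and Id2 and Msx1 at log2 ratios of 0.61 and 0.60. The FGF/ERK list had a median of -0.25, with Spry4 lower at 11.6 against 25.4 CPM and Ier3 higher at 3.49 against 0.777 CPM. Ligand and receptor genes of both pathways had a median of 0.12 with 3 of 22 higher, led by Bmp5 (6.77 against 2.43 CPM) and the antagonist gene Fst (26.5 against 12.2 CPM). Fitted over the 4 BMP4 libraries with edgeR's quasi-likelihood test, 885 of 16936 genes differed between 11 h and 5 h at an adjusted p under 0.05, 686 higher and 199 lower. The genes with the smallest p were the red cell membrane genes Ank1, Sptb and Ermap with Acp5 and Hand1, each at an adjusted p of 0.00136 by edgeR, with log2 fold changes of 3.87, 3.24, 5.10, 4.30 and 3.46. Lower genes with the smallest p were Cyp26b1, Aldh1b1, Gbx2, Dlx6os1 and 2610035F20Rik, at log2 fold changes of -1.62, -1.97, -1.42, -2.79 and -2.07. With DESeq2 size factors the count was 1636 and with the DESeq2 Wald test 1354. The fit has 1 residual degree of freedom, and each time holds 1 library with and 1 without an FGF. Both 5 h libraries lay nearer to 0 h untreated (59 and 39 genes at least 2-fold different) than to 96 h untreated (768 and 778). The difference between 11 h and 5 h therefore cannot be read as an effect of longer growth factor exposure alone.

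**Figure D2:**
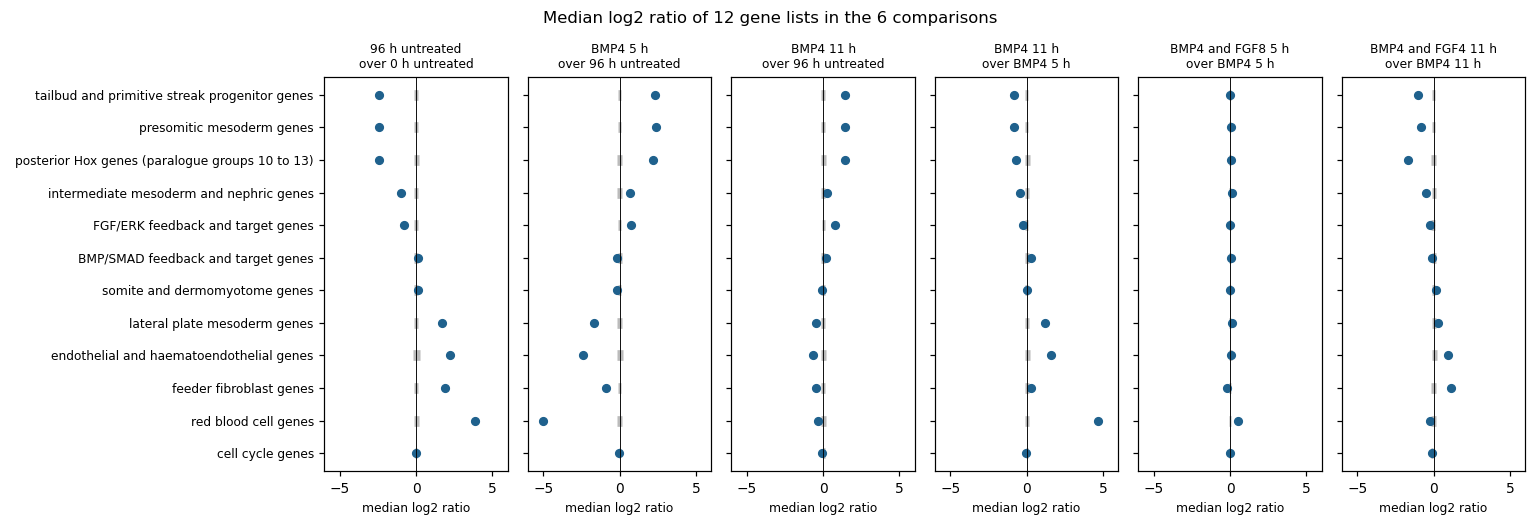
Median log2 ratio (x axis) of 12 gene lists (rows) in the 6 comparisons (panels), with grey bars for the central 95% of random lists matched on expression. Tailbud, presomitic and posterior Hox medians lie at -2.43, -2.42 and -2.43 after culture and at 2.34, 2.405 and 2.21 with BMP4 at 5 h, and with FGF8 at 5 h most points lie near 0.

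Addition of FGF8 to BMP4 for 5 h left nearly all genes within 2-fold of BMP4 alone, with 23 genes higher and 1 lower. The library labelled BMP4 with FGF8 5 h, like that of BMP4 5 h, lay nearer to 0 h than to 96 h untreated, with 39 genes at least 2-fold different from 0 h and 778 from 96 h. With 2 CPM added 14 were higher and 0 lower, with placement on the 96 h column alone 15 and 0, and with at least 5 CPM 0 were lower. Among the higher genes with a mean of at least 5 CPM were the globin genes Hbb-y (22.8 against 3.72 CPM), Hba-x (18.8 against 3.08), Hba-a1 and Hba-a2 (47.4 against 8.28) and Hbb-bh1 (15.03 against 3.07), and Filip1l (372 against 151), Cmss1 (386 against 164) and Tmtc2 (46.2 against 20.5 CPM). Filip1l and Cmss1 overlap on chromosome 16 (57353093 to 57573126 and 57302000 to 57606864). The ribosomal RNA precursor gene Rn45s was also higher, at 671 against 222 CPM. The 1 lower gene, Gper1, was at 0.375 against 1.499 CPM, and was named after its values were seen. The FGF/ERK list did not stand apart (median -0.02, 12.04th percentile, none of 17 called). Dusp6, an ERK phosphatase gene induced by FGF (chromosome 10, 99263231 to 99267489), was at 88.7 against 86.3 CPM, and Spry4 (chromosome 18, 38586247 to 38601415) at 24.8 against 25.4 CPM, a ratio of 0.940 to 1.01 by the counting interval.

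Tailbud and presomitic lists did not stand apart with FGF8 (medians -0.02 and 0.03), nor did the somite list (median 0.02), and T, Tbx6 and Msgn1 had log2 ratios of -0.08, -0.04 and -0.09. Small shifts placed several lists above random ones without any member at 2-fold, namely endoderm and notochord (median 0.34, Shh at 7.41 against 4.06 CPM and Foxa1 at 5.92 against 3.28), skeletal muscle (0.23), lateral plate (0.16), intermediate mesoderm (0.14) and BMP/SMAD genes (0.09, Id1 at 35.1 against 31.0 CPM). Red blood cell genes were higher in 6 of 13 cases (median 0.50). The fibroblast list stood below (median -0.21, Postn at 12.2 against 20.1 CPM), as did TGF-beta and serum response genes (median -0.15, Ltbp2 at 1.83 against 4.02 CPM).

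Addition of FGF4 to BMP4 for 11 h went with lower tailbud, presomitic and posterior Hox genes and higher endothelial and feeder fibroblast genes than BMP4 alone. The comparison is between libraries at different distances from the untreated ones, since the median share of the 0 h level over genes changed at 96 h was 0.455 with BMP4 alone and 0.0473 with FGF4. With FGF4 this share was 0.0902 for genes lower at 96 h and 0.387 for red blood cell genes. For other genes higher at 96 h it was -0.0986 (quartiles -0.473 and 0.210), where a negative share lies beyond the 96 h level. Over 96 h untreated, the library with FGF4 had a tailbud median of 0.30 and a posterior Hox median of -0.05. Endothelial and fibroblast lists had median levels of 10.6 and 44.9 CPM with FGF4, against 6.89 and 30.2 CPM at 96 h. The fibroblast list was chosen to mark the feeder layer. The share of feeder cells per library was not measured, here or in the other comparisons. For these genes, a change in the progenitors therefore cannot be told apart from a different share of feeder cells. Pax2 was at 1.69 against 26.3 CPM (13.95 to 17.4-fold lower by the counting interval), Tbx6 at 3.38 against 20.7, T at 11.2 against 45.2, Fgf17 at 1.83 against 14.01, Gad1 at 1.06 against 9.27 and Cdx4 at 5.28 against 23.1 CPM. Cdh5 was at 29.6 against 8.10 CPM, Tie1 at 16.9 against 4.56, Col1a1 at 362 against 107, Lum at 44.9 against 13.6, the matrix gene Tnc at 58.2 against 16.3, the mesothelial gene Upk3b at 11.1 against 2.78, the small heat shock gene Cryab at 11.9 against 3.004 and Gata4 at 14.8 against 3.81 CPM. In total 161 genes were at least 2-fold higher and 88 lower. Scaled by total counts the split became 215 higher and 69 lower, and with 2 CPM added 55 and 51. With at least 5 CPM 106 were higher, and with placement on the 96 h column alone 40 were lower.

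With FGF4, 8 of 16 tailbud genes (median -1.02), 9 of 19 presomitic genes (median -0.80), 8 of 10 posterior Hox genes (median -1.68), 3 of 12 trunk Hox genes (median -0.77) and 3 of 16 intermediate mesoderm genes (median -0.49) were lower. Msgn1 was at 0.838, Hes7 at 1.24, Dll3 at 6.96, Cyp26a1 at 3.08, Hoxd11 at 5.92 and Hoxc10 at 12.7 CPM. The FGF/ERK list stood below random lists, with a median of -0.22 and 1 of 17 lower, Etv4 at 9.77 against 21.0 CPM, while Spry4 and Dusp6 had log2 ratios of -0.74 and -0.12. The median level of its members was 21.6 CPM with FGF4, 21.7 CPM with BMP4 alone and 19.1 CPM at 96 h untreated. These levels are not paired by gene and nearly match between FGF4 and BMP4 alone. They therefore do not place the list against 96 h. WNT and Notch lists had medians of -0.17 and -0.24, with Dkk1 at 2.27 against 6.22 and Nrarp at 14.3 against 32.2 CPM. The BMP/SMAD list did not stand apart (median -0.09), and Id1, Msx1 and Msx2 had log2 ratios of -0.04, -0.22 and -0.14. Fibroblast genes were higher in 9 of 15 cases (median 1.14), endothelial genes in 8 of 17 (median 0.95), lateral plate genes in 2 of 17 (median 0.32), and TGF-beta and serum response genes had a median of 0.34 with none called. The somite list had a median of 0.14 with Tbx18 at 12.6 against 5.88 CPM, and the skeletal muscle list a median of 0.30 with Ttn at 9.74 against 2.85 CPM. Red blood cell genes had a median of -0.25 with none called, and Hbq1b, outside that list, was at 27.4 against 205 CPM.

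No gene was shared between those at least 2-fold higher with FGF8 at 5 h and those higher with FGF4 at 11 h, nor between those lower, where independent lists would share 0.266 and 0.00632. Fitted over the 4 BMP4 libraries, FGF addition gave 0 of 16936 genes at an adjusted p under 0.05 by edgeR's quasi-likelihood test, with 330 at an unadjusted p under 0.05 and 1 gene, Upk3b, by DESeq2 (log2 fold change 1.54, SE 0.290, adjusted p 0.00202). By edgeR the genes with the smallest p were Mpo, Upk3b, Col10a1, Eltd1 and Frem2 upward and Sdcbp2, Rpl24, 1700001D01Rik, Pygm and L3mbtl1 downward, all at an adjusted p of 1. The type of FGF and the time are confounded, so that a difference between FGF8 and FGF4 cannot be told apart from 1 between 5 h and 11 h.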

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

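The tests in this part were chosen after the results had been seen. A set of 12 genes went in opposite directions with FGF8 at 5 h and FGF4 at 11 h, each at least 2-fold, and the difference between these effects was not tested. The log2 ratios with FGF8 and with FGF4 were 1.02 and -1.42 for Arhgap21, 1.23 and -1.42 for Cmss1, 1.37 and -1.70 for D130009I18Rik, 1.298 and -1.47 for Filip1l, 1.09 and -1.56 for Il31ra, 1.40 and -1.36 for Mir6993, 1.60 and -1.67 for Rn45s, and 1.15 and -1.09 for Tmtc2. They were 2.54 and -2.86 for Scd4, 1.22 and -1.18 for C130050O18Rik, 2.97 and -2.88 for the globin gene Hbq1b, and -1.19 and 1.20 for Gper1. Scd4 was at 0.9905 (BMP4 5 h) and 0.9566 CPM (BMP4 with FGF4), against 7.052 to 10.06 CPM in the other libraries. In the same order, C130050O18Rik was at 0.3226 and 0.3189 against 1.303 to 1.497 CPM. Gper1 was at 1.499 and 1.233 against 0.1401 to 0.4114 CPM. These levels group libraries that share neither time nor FGF addition, and the cause was not tested. Hbq1b lacked this grouping (0.2726 and 27.42 CPM). Between BMP4 at 5 h and at 11 h over 96 h untreated, 0 genes were called in opposite directions.

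For 7 of the genes with opposite FGF ratios, reads of ribosomal RNA are a candidate source, since Rn45s is among the 12, at 328, 413, 222, 1043, 671 and 328 CPM in the order 0 h, 96 h, BMP4 5 h, BMP4 11 h, BMP4 with FGF8 and BMP4 with FGF4. These 7 all lay between both 5 h libraries at 0 h and within 1.174-fold of it with FGF4, as Rn45s does. At 96 h, however, all 7 lay above BMP4 with FGF8 (Arhgap21 at 324 against 277 CPM, Filip1l at 376.5 against 371.7 CPM). Rn45s lay below it there (413 against 671 CPM). No ribosomal sequence was matched, so this source stays open for the 7. For Scd4, Hbq1b, C130050O18Rik and Gper1 it is argued against, as they differed at least 2.996-fold between 0 h and BMP4 with FGF4. The split between these genes and the 7 was made after the values were seen. For Gper1 and C130050O18Rik, which neighbour each other on chromosome 5 (139423151 to 139427800 and 139405280 to 139415623), reads moving between both genes may account for the values. The sum of the pair varied 1.17-fold over the 6 libraries, from 1.55 to 1.82 CPM, while Gper1 alone varied 10.7-fold. Opposite effects of the 2 FGFs or times remain untested, and the FGF/ERK list's median of -0.022 with FGF8 at 5 h does not decide it.

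The libraries labelled BMP4 5 h and BMP4 with FGF8 5 h lay close to 0 h untreated, with 59 and 39 genes at least 2-fold different, and far from 96 h untreated, with 768 and 778. For BMP4 5 h, wrong gene names from the placement are argued against, because with rows placed on the 96 h column alone 47 genes still differed from 0 h and 490 from 96 h. A label that does not match the culture history and a return of cultured cells to their first state cannot be told apart, since 96.8% of the 865 genes changed at 96 h lay nearer to 0 h (98.4% with FGF8), which both would give, and no untreated library of 101 h is among the conditions. A response to BMP4 is not decided by the BMP/SMAD list, whose median over 96 h was -0.15 and which lacks Smad6 and Smad7. The median level of its members was 8.33 CPM with BMP4 at 5 h against 8.63 CPM at 0 h. Id1, Id2 and Id3 were at 31.0, 49.0 and 47.7 CPM, against 31.1, 49.8 and 48.8 CPM at 0 h, so these genes showed no rise over 0 h. If the red blood cell transcripts fell within the same cells, their median fall in 5 h would allow a half-life of at most 1.00 h even with synthesis stopped, and no half-life was measured here. The median level of this list was 40.9 CPM at 96 h, 0.286 CPM with BMP4 at 5 h and 29.1 CPM with BMP4 at 11 h. If these labels hold, such a fall would have to be followed by a rise by 11 h. With 1 library per condition this is not settled.

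For most genes changed at 96 h, the BMP4 11 h library lay between both untreated libraries, and the share of the 0 h level in it was computed on the linear scale. Its median was 0.423 for the 328 genes lower at 96 h and 0.469 for 524 genes higher at 96 h outside the red blood cell list, a difference of 0.0456, as a mixture in 1 proportion would give for these genes. The 13 red blood cell genes had a median share of 0.226 (quartiles 0.0552 and 0.287, against 0.355 and 0.571 for the other higher genes), which argues against the same proportion for them. A mixture and nothing else is also argued against, as 95 genes lay at least 2-fold above both untreated libraries. Simulated mixtures with a coefficient of variation of 0.2 gave at most 10. Of the 95, 32 had both counting intervals above 4-fold (Trp53cor1 at 11.9 CPM against 0.521 and 0.453). In the simulated mixtures 0 genes were at least 4-fold above both by the ratio with 0.5 CPM added. That rule uses no interval, so 32 and 0 are not like for like. An intermediate state of every cell stays open, since 93.1% of the changed genes lay between both libraries, a share that the placement favours, and bulk RNA gives no value per cell.

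Rows that could not be tied to a gene name held 0.117% of the counts of BMP4 5 h, 0.121% of BMP4 11 h, 0.140% of BMP4 with FGF8 and 0.136% of BMP4 with FGF4, and 0% in both untreated libraries.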

How the results depend on the processing

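Placement margin, placement on 96 h alone, halved counts and all named rows were chosen after seeing the data. With DESeq2 size factors, total counts, no filter, the fold alone, halved counts or a margin of 10, every count of genes at least 2-fold different stayed within 1.5 times its main value. With the fold alone or halved counts, these counts did not change. The filter of at least 5 CPM tests fewer genes and gave 349 higher and 211 lower for 96 h over 0 h, 286 lower for BMP4 5 h over 96 h, 178 higher for BMP4 11 h over 96 h, 203 higher and 26 lower for BMP4 11 h over 5 h, 0 lower with FGF8 and 106 higher with FGF4. Adding 2 CPM, which shrinks ratios of weakly expressed genes, gave, in the order higher and lower, 295 and 185 (96 h over 0 h), 187 and 258 (BMP4 5 h), 140 and 12 (BMP4 11 h), 143 and 18 (11 h over 5 h), 14 and 0 (FGF8), and 55 and 51 (FGF4), with 78 and 12 shared by both BMP4 comparisons. Placement on the 96 h column alone keeps fewer changed genes and gave 188 lower for 96 h over 0 h, 189 higher for BMP4 5 h, 20 lower for BMP4 11 h, 16 lower for 11 h over 5 h, 15 higher and 0 lower with FGF8, 40 lower with FGF4, and 77 and 19 shared. In the 4 BMP4 libraries, time gave 1636 genes with DESeq2 size factors and 1354 with the DESeq2 Wald test, and FGF addition gave 1 with the latter, and the cause was not tested. The retinoic acid list's median reversed to 0.015 with at least 5 CPM for 96 h over 0 h, and with placement on 96 h alone to 0.070 there, to -0.15 for BMP4 5 h and to -0.0077 for BMP4 11 h; the cause was not tested. Of the other list medians, 1170 stayed on their side of the threshold, 29 lost and 21 gained it. Of 2413 named-gene values under alternatives 3 changed sign, the largest with a main log2 ratio of 0.12 in size, and 510 moved beyond their counting interval, 327 of them with 2 CPM added, 181 with total counts and 2 with DESeq2 size factors. Leaving out mitochondrial genes was not run, as none was analysed here. Depth limits the precision of weakly expressed genes, and each condition had 1 library.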

Other observations

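Against 0 h untreated, a comparison chosen after seeing the data, fibroblast list genes were higher in 6 of 15 cases with BMP4 at 5 h (median log2 ratio 0.78) and in 3 of 15 with FGF8 added (0.62), and TGF-beta and serum response genes in 5 and 2 of 11 (0.84 and 0.61). No tailbud, presomitic or posterior Hox gene was called in either library, while these lists stood below random lists, with medians of -0.15, -0.13 and -0.26 for BMP4 at 5 h and -0.16, -0.09 and -0.14 with FGF8 added. With BMP4 at 5 h, the proteoglycan gene Bgn was at 25.5 against 2.93 CPM at 0 h, Postn at 20.1 against 2.60, Tnc at 10.7 against 1.499, Col12a1 at 16.4 against 3.18, Tagln at 26.5 against 7.51 and Acta2 at 30.1 against 12.3 CPM. With FGF8 added, Bgn was at 18.3, Postn at 12.2 and Col12a1 at 10.2 CPM. Cyp26b1, which degrades retinoic acid, was at 15.8 CPM with BMP4 at 5 h against 6.83 at 0 h and 3.24 at 96 h. BMP4 at 5 h differed at least 2-fold from 0 h in 47 genes upward and 12 downward, BMP4 with FGF8 in 36 and 3, BMP4 at 11 h in 452 and 66, and BMP4 with FGF4 in 776 and 253. Against 96 h untreated, BMP4 with FGF4 at 11 h was higher in 159 genes and lower in 12.

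With BMP4 at 11 h and with FGF4 added, Trp53cor1 was at 11.9 and 4.90 CPM and Sesn2 at 27.4 and 16.7 CPM, while in the other 4 libraries Trp53cor1 lay between 0.453 and 0.618 CPM and Sesn2 between 7.05 and 8.23 CPM. The p53 target list did not stand apart between these 2 libraries (median -0.036, 33.35th percentile, 1 of 15 lower with FGF4). These genes, Gas6 and the sex-linked genes were picked for display here after their values were seen, though Sesn2 and the sex-linked genes belong to lists fixed beforehand. Gas6 was at 12.2 CPM with FGF4, against 4.98 with BMP4 alone at 11 h, 0.818 at 0 h and 2.52 at 96 h. It was at 5.425 CPM with BMP4 at 5 h and 2.965 CPM with FGF8 added. Xist was at 124, 79.8, 212, 115, 205 and 213 CPM in the order 0 h, 96 h, BMP4 5 h, BMP4 11 h, BMP4 with FGF8 and BMP4 with FGF4, and the Y-linked gene Ddx3y at 19.5, 23.5, 14.3, 21.0, 14.7 and 19.7 CPM.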
